A study of Homo sapiens with 74 samples.

How the data were processed

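Chromatin accessibility was measured by ATAC-seq in HAP1 cells. Per the labels, cells of each line were permeabilised with digitonin and tagged with the TDE1 transposase. The labels listed 74 samples, of which 72 were matched to a column of the deposited count tables by title. For 2 wild-type libraries, replicates 3 and 4, no column was found, and they were not analysed here. The count tables also held 2 columns of libraries that the labels do not list, and these were not used here. The deposited count tables hold counts, whole numbers of reads per region and library that the authors had not scaled for depth. The knockout table has 145536 regions and 56 libraries, and the knockdown table has 145730 regions and 16 libraries. All 145536 regions of the knockout table stand in the knockdown table with the same coordinates, and the other 194 lie on unplaced or random contigs. Regions are 501 to 3982 base pairs long, with a median of 622. The submitters' notes name Bowtie2 2.2.4, Picard 1.118, MACS2 2.1.1.20160309 and the build hg19, without a role or order for each tool. How the list of regions was merged and how reads were counted is not stated, nor whether starts count from 0 or 1, so coordinates are printed as the files give them. A further deposited table of the authors holds normalized accessibility of 48 libraries over 145533 regions on a scale taken as log2 from its slope against log2 CPM, counts scaled to library size. Its method is not stated, and its values show a correction that differed between regions. It was used only for an alternative test.

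Samples were grouped by the knocked-out gene, clone and knockdown in the labels. Titles name the knockdowns as short hairpin and another field names them as small interfering RNA, so only the word knockdown is used. The knockout libraries fall into 2 sets by accession range and the form of their titles. Set 1 holds 23 clones and wild-type replicates 1 and 2, and set 2 holds 1 clone each of ARID1B, BCL7B and SMARCC2 with wild-type replicates 5 and 6. The labels give no dates, so the sets are an inferred technical grouping. Each clone was compared with the wild type of its own set, and a gene with 2 clones was tested as their mean. Total counts per library were 7855389 to 12422345 in set 1, 5085811 to 7331537 in set 2 and 5355899 to 12432292 in the knockdown table. The median count per region was 20 to 43 in the knockout libraries and 17 to 36 in the knockdown libraries. Reads carry no molecular identifiers, so floors given for groups without reads cover counting error only. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries.

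Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, TMM normalization, the default expression filter and Benjamini-Hochberg adjustment over all regions tested, at an adjusted p of 0.05. A region past that threshold is said to be called. The knockout fit had 1 coefficient per clone and per wild-type set, 28 residual degrees of freedom and 145532 regions. The knockdown fit had 8 groups, 8 residual degrees of freedom and 145617 regions, and interactions were differences of differences within it. Knockouts of PBAF subunits were set against knockouts of BAF subunits on counts summed per knocked-out gene of set 1, with 7 residual degrees of freedom and 145526 regions. Tests are 2-sided. Log2 fold changes are given with their standard error (SE), and accessibility in CPM with the standard deviation (SD) between libraries. For a group with no reads, a lower bound of the fold was computed with 3 counts over the group. Correlations run across the 72766 regions of above-median accessibility, and regions are not independent replicates. For clones that share wild-type libraries, and for knockdowns that share a control group, 5 data sets of unchanged groups with a shared control were simulated. They show the correlation that sharing a control gives. The control libraries were simulated too, so the observed values of the actual controls did not enter. Overlaps expected by chance were the product of the counts of calls over all regions, and were also summed over 20 bins of mean accessibility. The simulated data sets gave at most 2 called regions for any clone. Power was tested on simulated data with 200 changed regions, all drawn from those of above-median accessibility, so power at less accessible regions was not measured. The groups, tests, rule for naming regions and most of the alternative settings were set before the data were examined.

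Regions named in the text passed the threshold, lay above the median accessibility, and had every library of the first group on the same side of every library of the second. They were ranked by log2 fold change, and up to 3 per direction are named for the main comparisons and 1 per direction for the others. Regions chosen in another way are said to be so. The reference at hand is of a later genome build than hg19. Regions were therefore not assigned to genes, and 18 fixed gene lists, promoter classes, accessibility at the targeted genes and markers of other cell types were not tested. The alternatives were RLE size factors, cyclic loess offsets, no expression filter, DESeq2 1.42.0, a 2-fold minimum, the replicate number as a block, each library left out in turn, pooled wild type, the other knockouts as reference, single clones, chromosomes removed, and limma 3.58.1 on the deposited normalized values. Alternatives added later removed stretches without reads and windows of 5 Mb with shifted counts, and centred the normalized differences on their median. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the figures.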

Results

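Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA, in HAP1, a near-haploid human line that came from a chronic myeloid leukaemia. The series removes single subunits of the BAF (SWI/SNF) complexes, which move nucleosomes with the energy of ATP, and so asks which regions depend on which subunit. The knockout table held 22 knocked-out genes in 26 clones, with 2 libraries per clone, and 4 wild-type libraries. The knockdown table held 8 groups of 2 libraries in which ARID2, SMARCA4, both or a control were knocked down in wild-type, ARID2 knockout or SMARCA4 knockout cells. Total counts per library ranged from 5085811 to 12422345 in the knockout table and from 5355899 to 12432292 in the knockdown table. Counts of the 2 libraries of a group correlated at r = 0.859 to 0.932 across regions in the knockout table and at 0.845 to 0.919 in the knockdown table. Coordinates are in hg19.

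Against wild type, 31838 of 145532 regions were called in the knockout of SMARCA4, the ATPase of the complex. The knockout of ARID1A, a DNA-binding subunit of the canonical BAF form, had 18281, and that of SMARCC1, a core scaffold subunit, had 7555. These 3 knockouts made up 70.1% of all calls. The 18 knockouts other than these and ARID2 ranged from 75 regions for DPF1, a plant homeodomain finger protein, to 4683 for ARID1B, the paralog of ARID1A. Their median was 853.5, or 285.5 without wild-type replicate 1 and 321.5 without wild-type replicate 2. The DPF1 count was 20 to 45 without any 1 of its own or the wild-type libraries of set 1, and the ARID1B count was 2880 to 3115 without clone 5 replicate 2, clone 7 replicate 1 or wild-type replicate 2, 5 or 6. ARID1B and BCL7B were tested as the mean of 2 clones that differed. Alone, ARID1B clone 7 had 13417 and clone 5 had 400, and BCL7B clone 8 had 7030 and clone 10 had 1081. The order of the knockouts and the 70.1% share thus depended on the clones. In all, 43431 regions (29.8%) were called in at least 1 knockout, 23136 of them in exactly 1 knockout and 2072 in 5 or more. Regions lower in at least 1 knockout and higher in another numbered 3977. Genes other than SMARCA4, ARID1A, ARID1B and BCL7B had 1 clone each, so there gene loss cannot be told apart from changes of the clone. The wild-type libraries of the 2 sets differed at 8481 regions with no gene removed. Lower regions outnumbered higher ones in 11 of the 22 knockouts, a tally that depended on the scale and the reference: it was 2 of 21 on the authors' normalized values (DPF1 and SMARCA2), 17 of 21 on those values relative to their median, 20 of 22 with all wild type pooled, 3 of 22 against the mean of the other knockouts and 20 of 21 without wild-type replicate 2.

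**Figure D1:**
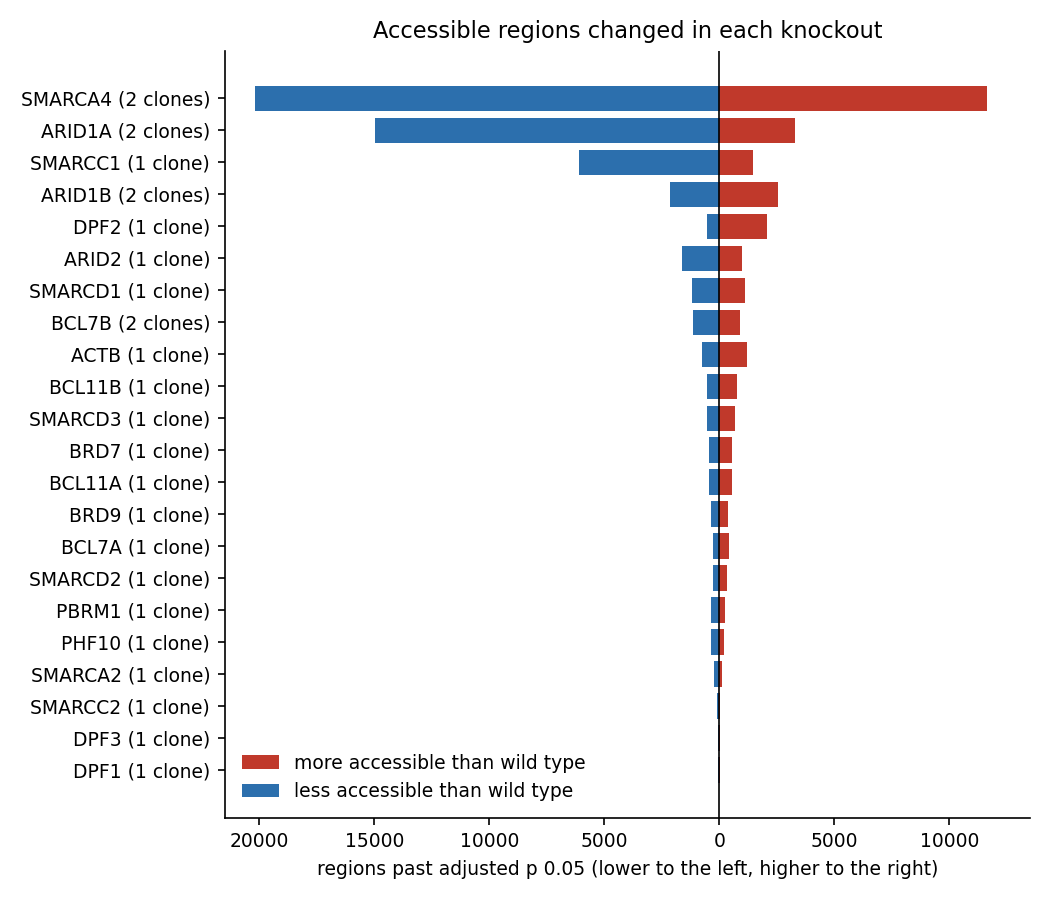
Regions called higher (to the right) and lower (to the left) than wild type in each of the 22 knockouts, on a linear axis of region counts. SMARCA4 had 20200 lower and 11638 higher regions, and DPF1 had 55 lower and 20 higher.

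In the SMARCA4 knockout, 20200 regions were lower and 11638 higher than in wild type. On chromosome 21, the region from 28419401 to 28420301 held 1.52 ± 0.468 CPM (SD, n = 4) against 28.3 ± 4.33 (n = 2) in wild type, a log2 fold change of -4.22 (SE 0.22, adjusted p = 5.95e-39). The regions on chromosome 10 from 65700147 to 65700787 and on chromosome 11 from 55198484 to 55199439 fell by 4.17 (SE 0.239) and 4.13 (SE 0.199) on the log2 scale. The region on chromosome 1 from 97063749 to 97064425 rose to 32.9 ± 4.02 CPM (n = 4) from 2.56 ± 0.912 (n = 2), a log2 fold change of 3.66 (SE 0.298, adjusted p = 7.69e-22), and those on chromosome 15 from 96389013 to 96389681 and on chromosome 13 from 71533364 to 71534046 rose by 3.28 and 3.23. Of the higher regions, 61.9% lay among the 25% most accessible regions, against 38.4% of the lower ones (odds ratio 2.61, 95% confidence interval 2.48 to 2.73), but with cyclic loess offsets the ratio was 0.916 and among calls of at least 2-fold it was 0.501. The split of calls depended on the scale. On the authors' normalized values the median region was 0.34 higher on the log2 scale and 24.1% of 34757 called regions were lower, and relative to that median 27820 regions were called, of which 71.3% were lower. Fewer regions were called without wild-type replicate 1 (19713) or without wild-type replicate 2 (20254).

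In the ARID1A knockout, 14983 regions were lower and 3298 higher, so that 82% of the calls were losses. The chromosome 21 region from 28419401 to 28420301 was also its most reduced, at 2.33 ± 0.497 CPM (SD, n = 4) against 28.3 ± 4.33 (n = 2), a log2 fold change of -3.61 (SE 0.206, adjusted p = 2.41e-34). The chromosome 10 region from 65700147 to 65700787 and the chromosome 3 region from 163631982 to 163633001 both fell by 3.16 on the log2 scale (SE 0.215 and 0.223). On chromosome 2, the region from 165972142 to 165973254 rose to 20.2 ± 3.23 CPM from 2.41 ± 1.49, a log2 fold change of 3.1 (SE 0.296, adjusted p = 1.09e-16), and it rose by 2.91 in the SMARCA4 knockout as well. The chromosome 3 regions from 6197388 to 6198460 and from 188665047 to 188666005 rose by 2.89 and 2.78 in the ARID1A knockout and by 2.84 and 2.39 in the SMARCC1 knockout. On the authors' normalized values the median region was 0.22 higher and 35.5% of 21985 called regions were lower, and relative to that median 19261 were called, of which 72% were lower. Without wild-type replicate 1 the count was 9674.

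In the SMARCC1 knockout (n = 2), 6094 regions were lower and 1461 higher. The region on chromosome 10 from 130963131 to 130963772 rose to 13.9 ± 2.21 CPM (SD, n = 2) from 1.68 ± 0.511 (n = 2), a log2 fold change of 3.02 (SE 0.359, adjusted p = 3.81e-11), and that on chromosome 4 from 77409390 to 77410392 rose by 2.93. The 3 most reduced regions had no reads: chromosome 10 from 89577557 to 89578799 was at least 163-fold lower than wild type, and chromosome 9 from 82543776 to 82545073 and from 82282617 to 82283308 were at least 73.7-fold and 46.2-fold lower. They lay in stretches of neighbouring regions that had almost no reads in this clone, 12 regions over 226 kb on chromosome 10 and 37 regions over 805 kb on chromosome 9. On the authors' normalized values the median region was 0.185 higher and 44.2% of 8331 called regions were lower, and relative to that median 8710 were called, of which 75.1% were lower. The count was 3303 without wild-type replicate 1, 5028 without wild-type replicate 2, 3955 without SMARCC1 replicate 1 and 3959 without SMARCC1 replicate 2.

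ARID2 is the DNA-binding subunit of PBAF, the form of the complex that also holds PBRM1, BRD7 and PHF10. Its knockout, in 1 clone, had 1610 lower and 992 higher regions (n = 2). On chromosome 2 the region from 205911874 to 205912636 fell to 0.202 ± 0.286 CPM (SD, n = 2) from 7.04 ± 1.16 (n = 2), a log2 fold change of -5.01 (SE 0.49, adjusted p = 7.72e-15). This region also lay in a stretch with almost no reads in the SMARCA2 clone. The regions on chromosome 16 from 80079970 to 80080676 and on chromosome 7 from 146688390 to 146689319 fell by 4.02 and 3.53 on the log2 scale, and both also fell in the SMARCA4 knockout, by 3.71 and 2.82. Higher regions were led by chromosome 10 from 22675264 to 22675947, at 12.1 ± 4.15 against 1.55 ± 0.834 CPM and a log2 fold change of 2.92 (SE 0.381, adjusted p = 4.65e-09), chromosome 6 from 158843514 to 158844231 (2.45) and chromosome 8 from 37991418 to 37992212 (2.37). On the authors' normalized values the median region was 0.12 higher and 40.6% of 4448 called regions were lower, and relative to that median 4628 were called, of which 66.2% were lower. The count was 880 without wild-type replicate 1, 1371 without wild-type replicate 2 and 1044 without ARID2 replicate 1.

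Several of the remaining knockouts shared their strongest regions. Those named here share the wild-type libraries of set 1, so chance values of these libraries can recur in several knockouts. In the DPF2 knockout, 2060 of 2604 called regions were higher, led by chromosome 6 from 63443519 to 63444775 (log2 fold change 2.78), which was also the highest region of the SMARCD1 knockout (3.09). The DPF2 count was 345 without DPF2 replicate 1, 496 without wild-type replicate 2 and 1236 without wild-type replicate 1. BCL11A and BCL11B, related zinc-finger proteins, shared their highest region, on chromosome 12 from 62114063 to 62114710 (2.74 and 2.91). BCL7A and DPF3 shared chromosome X from 145604709 to 145605379 (2.64 and 2.58). The highest region of SMARCD2 lay on chromosome 21 from 32931185 to 32932078 (3.31), that of BRD7 on chromosome 19 from 8590091 to 8590992 (3.16), and that of BRD9 on chromosome X from 153138847 to 153139516 (2.66). In the BRD9 clone the regions of chromosome X from 150 to 155 Mb were shifted together, by a median of 0.93, and all 118 called there were higher. The lowest regions of BCL11A, BCL11B, BCL7A, PHF10 and SMARCD3 lay in the chromosome 10 stretch with almost no reads described for SMARCC1, where PHF10 was at least 177-fold and BCL11A at least 139-fold lower than wild type.

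For 4 genes 2 clones could be compared. The SMARCA4 clones 4 and 6 shared most of their lost regions. Of 16266 lower regions in clone 4 and 14978 in clone 6, 11198 were lower in both, against 1670 by chance (the product of the counts over all regions). Of 9165 and 7977 higher regions, 5430 were higher in both, against 502. The ARID1A clones 3 and 10 shared 7203 lower regions (790 by chance) and 963 higher ones (35.2 by chance). Their effects correlated across regions at r = 0.892 (rho = 0.876) for SMARCA4 and at r = 0.855 (rho = 0.822) for ARID1A. Unchanged clones simulated with shared wild-type libraries, themselves simulated, reached 0.495 and 0.494 with a covariance of 0.0425 and 0.0422. The observed covariances were 0.534 and 0.335. ARID1B clone 7 of set 1 had 13417 called regions and clone 5 of set 2 had 400, and the clones correlated at r = -0.0515. BCL7B clone 8 of set 1 had 7030 and clone 10 of set 2 had 1081, with r = -0.134. The ARID1B clones shared 82 lower regions (9.5 by chance) and 20 higher ones (6.15 by chance), and 53 were called in opposite directions (21.2 by chance). The BCL7B clones shared 94 lower (10.7 by chance) and 26 higher regions (9.79 by chance), and 128 were called in opposite directions (31.7 by chance). Calls were not spread evenly over accessibility, and within 20 bins of mean accessibility the chance values of lower regions were 2740 (SMARCA4), 1560 (ARID1A), 14.6 (ARID1B) and 17.2 (BCL7B), with 31.7 and 49.9 for the opposite calls of ARID1B and BCL7B. The counts for ARID1B and BCL7B rest mostly on the clones of set 1. The wild-type libraries of the 2 sets themselves differed at 8481 regions.

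Among the 210 pairs of set 1 knockouts, SMARCA4, ARID1A and SMARCC1 lost the most regions together. ARID1A and SMARCA4 were both lower at 11042 regions (2080 by chance), which is 73.7% of the ARID1A losses. SMARCC1 shared 75.2% of its losses with ARID1A (4584 regions, 627 by chance) and 75% with SMARCA4 (4570, 846 by chance), and 3886 regions were lower in all 3. ARID2 shared 73.9% of its losses with SMARCA4 (1189 regions, 223 by chance), and 158 with PBRM1 (3.91 by chance). Within bins of accessibility the chance values were 3320 for ARID1A and SMARCA4, 1140 and 1380 for SMARCC1 with ARID1A and SMARCA4, 358 for ARID2 and SMARCA4, and 7.53 for ARID2 and PBRM1. These knockouts share their wild-type libraries, so part of each overlap may come from shared controls. Effects correlated at r = 0.756 for ARID1A and SMARCA4, where unchanged knockouts simulated with shared, simulated controls gave 0.662, and the covariance was 0.343 against 0.0424 simulated. For SMARCA4 and SMARCC1, r was 0.583 against 0.581 simulated, for ARID2 and SMARCA4 0.453 against 0.578, and for ARID2 and SMARCD2 0.464 against 0.508, so these correlations with wild type as reference lay near or below those of shared controls alone. Their covariances were 0.238, 0.146 and 0.0712 against 0.0424 simulated for each. With the median of all knockouts as reference in place of wild type, the correlations were 0.722 for ARID1A and SMARCA4, 0.644 for ARID1A and SMARCC1, 0.533 for BCL11A and BCL11B, 0.352 for ARID2 and SMARCA4, 0.309 for BRD7 and PBRM1, and 0.3 for ARID2 and SMARCD2, where simulated pairs had a median of -0.0236.

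**Figure D2:**
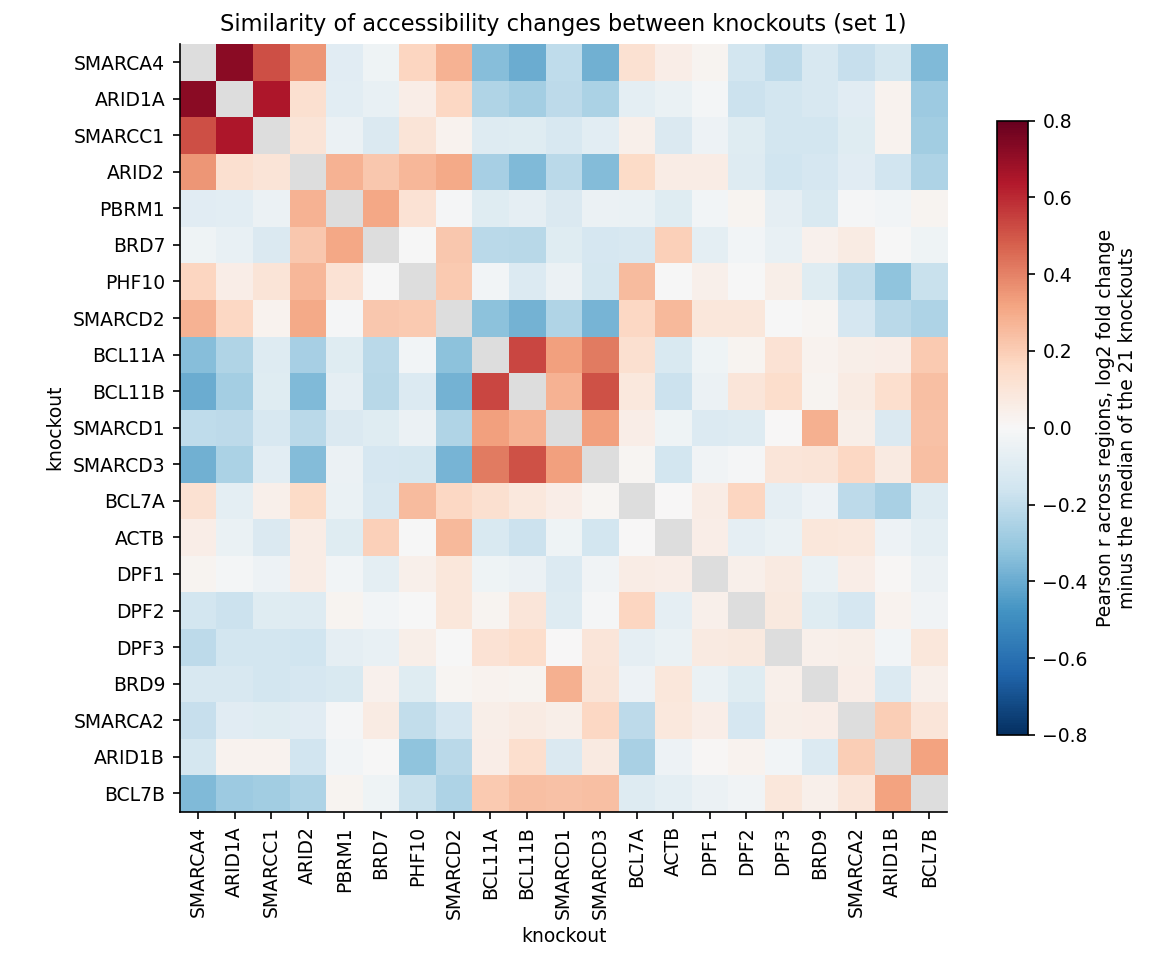
Pearson correlation across 72766 regions of accessibility changes for each pair of the 21 set 1 knockouts, each change taken from the median of all knockouts. ARID1A and SMARCA4 correlate at 0.722 and BCL11B and SMARCD3 at 0.509.

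Paralogous subunits were compared directly. SMARCA4 and SMARCA2, the alternative ATPases, differed at 37079 regions, 22323 of them lower in the SMARCA4 knockout. The SMARCA2 knockout itself had 341 called regions against wild type, and 111 to 185 without any 1 of its own or the wild-type libraries of set 1. ARID1A and ARID1B differed at 16757 regions, 13850 lower in the ARID1A knockout. BRD9, a subunit of the non-canonical form, and BRD7 differed at 3235 regions (1841 lower in the BRD9 knockout), SMARCC1 and SMARCC2 at 1643 (1342 lower in the SMARCC1 knockout), and SMARCD1 and SMARCD3 at 1298 (906 lower in the SMARCD1 knockout). SMARCC2 and ARID1B clone 5 lay in set 2, so the contrast of SMARCC1 with SMARCC2 rests on separate wild-type libraries and that of ARID1A with ARID1B does so in part, with 2 ARID1B clones that differed from each other at 7235 regions. These directions were checked with TMM and RLE scaling only.

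Knockouts of 4 PBAF subunits (ARID2, PBRM1, BRD7, PHF10) were compared with knockouts of 5 subunits of canonical BAF (ARID1A, ARID1B, DPF1, DPF2, DPF3). At 2 of 145526 regions the PBAF knockouts were higher, and none was lower. On chromosome X, the region from 102611074 to 102612335 held 22.8 ± 0.858 CPM (SD, n = 4) against 4.84 ± 0.319 (SD, n = 5), a log2 fold change of 2.24 (SE 0.128, adjusted p = 2.56e-05). On chromosome 4, that from 112694899 to 112695491 held 6.69 ± 0.504 against 2.32 ± 0.277, a log2 fold change of 1.53 (SE 0.165, adjusted p = 0.0307). Both regions were higher in 4 of 4 PBAF knockouts than in every BAF knockout, which adds no support, since they were picked by a test of these same values. Wild type of set 1 lay between the groups, at 8.25 ± 1.51 CPM (n = 2) on chromosome X and 3.58 ± 0.157 on chromosome 4. At an unadjusted p of 0.05 the test gave 12149 regions. On simulated data it found 40.3% of 2-fold and 98.5% of 4-fold changes at regions of above-median accessibility, and also called 10 unchanged regions. Only 1 region was called without any of ARID1B, ARID2, BRD7, DPF1, DPF2, DPF3 or PBRM1, and 5 were called without ARID1A.

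**Figure D3:**
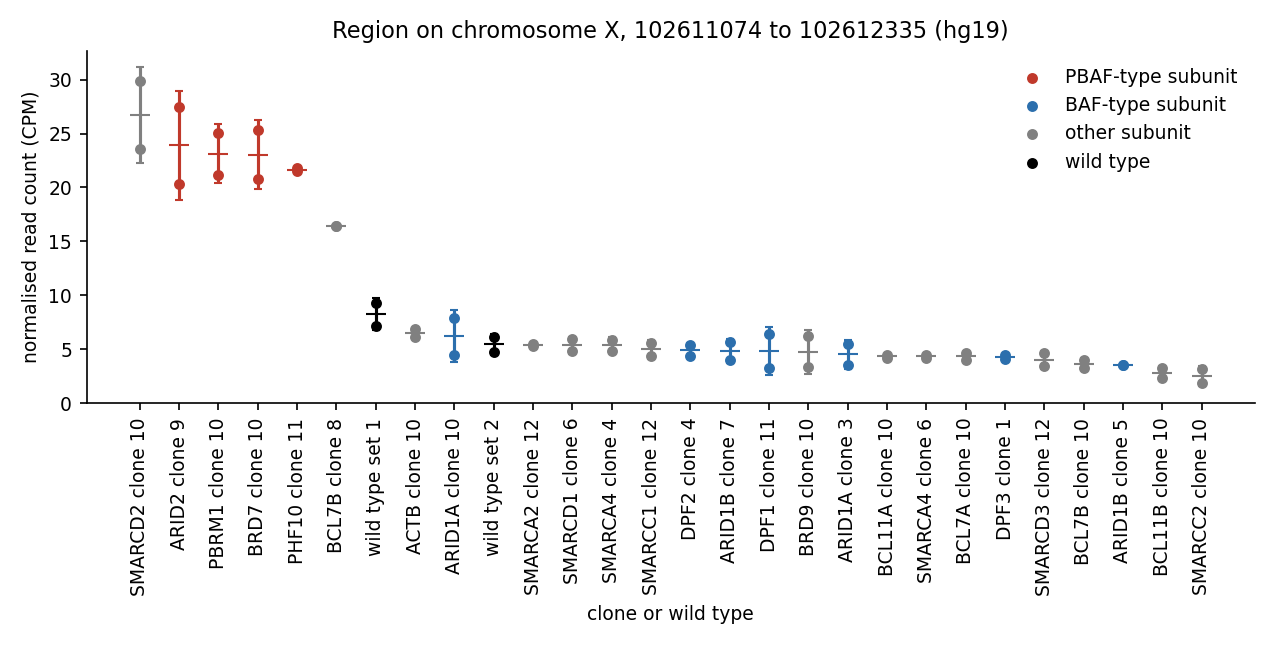
Accessibility in CPM of the region on chromosome X from 102611074 to 102612335 in the knockout table by clone, with libraries as points, the mean of 2 as a line and the SD as a bar (PBAF subunits red, BAF subunits blue, others grey, wild type black). SMARCD2 (26.7), ARID2 (23.9), PBRM1 (23.2), BRD7 (23.1) and PHF10 (21.7) have the highest means, and wild type of set 1 has 8.25.

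In the knockdown table, knockdown of SMARCA4 in wild-type cells lowered 7216 of 145617 regions and raised 1125 (n = 2 per group). The region on chromosome 4 from 171226654 to 171227283 fell to 1.04 ± 0.536 CPM (SD) from 14.4 ± 1.78, a log2 fold change of -3.7 (SE 0.469, adjusted p = 4.82e-07). On chromosome 1 the region from 202427666 to 202429284 rose to 29 ± 8.91 CPM from 2.82 ± 1.26, a log2 fold change of 3.33 (SE 0.448, adjusted p = 1.16e-06), and rose by 3.43 in the double knockdown. Knockdown of SMARCA4 and ARID2 together lowered 5831 regions and raised 900, and its most reduced region, on chromosome 18 from 69292664 to 69293508, fell to 1.28 ± 0.86 CPM from 13.8 ± 0.383, by 3.5 on the log2 scale (SE 0.442, adjusted p = 3e-07). The SMARCA4 and double knockdowns shared 4138 lower regions (289 for independent lists, and 449 within bins of accessibility). Their effects correlated at r = 0.865 (rho = 0.837), where simulated data gave 0.488, with a covariance of 0.381 against 0.073 simulated. Part of the overlap may come from the control group that both used. The SMARCA4 knockdown count fell to 3587 without control replicate 1, 3432 without control replicate 2, 2963 without SMARCA4 knockdown replicate 1 and 3874 without its replicate 2. The double knockdown count fell to 2520 and 2604 without control replicates 1 and 2, and to 1569 and 2486 without its own replicates 1 and 2. With the replicate number as a block, the counts of the SMARCA4 and double knockdowns were larger, as given with the processing.

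Knockout cells that received the control knockdown gave a second measurement of each knockout, with separate libraries and controls. The labels do not name their clones. The SMARCA4 knockout cells had 0 counts in the same stretch of chromosome 16, from 78830044 to 79100975, as SMARCA4 clone 6. ARID2 had 1 clone in the knockout table. The same clones may thus have been used, and changes particular to a clone would then recur as well. SMARCA4 knockout cells had 12024 lower and 2173 higher regions, and ARID2 knockout cells had 544 lower and 65 higher. For SMARCA4, 8972 of the lower regions (74.6%) were also lower in the knockout table (1670 by chance, 2570 within bins of accessibility) and 1116 of the higher regions (51.4%) were also higher (174 by chance), and the effects correlated at r = 0.785 (rho = 0.706). For ARID2, 279 lower regions (51.3%) were shared (6.02 by chance, 10.5 within bins) and 21 higher ones (32.8%, with 0.436 by chance), with r = 0.404 (rho = 0.344). The chromosome 1 region from 97063749 to 97064425 was the most raised of the SMARCA4 knockout in both tables, here by 4.26 on the log2 scale (SE 0.456, adjusted p = 3.62e-10), at 19.5 ± 5.72 against 1.03 ± 0.358 CPM (SD, n = 2 per group). On chromosome 11 the region from 16841737 to 16842452 had no reads in SMARCA4 knockout cells and was at least 43.6-fold lower than the 8.48 ± 2.35 CPM of wild type. In ARID2 knockout cells, chromosome 7 from 146976625 to 146977607 fell to 1.82 ± 0.0785 CPM from 37.1 ± 1.88, a log2 fold change of -4.34 (SE 0.465, adjusted p = 3.09e-09). The SMARCA4 knockout count fell to 8064 and 8825 without control replicates 1 and 2, and to 6249 and 7583 without its own replicates 1 and 2. The ARID2 knockout count fell to 167 and 160 without the wild-type control replicates 1 and 2, and to 102 and 182 without its own replicates 1 and 2, and was 1196 with cyclic loess offsets. With the replicate number as a block the ARID2 knockout count was larger too, as given with the processing, so its size depended on that choice.

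The series title speaks of synthetic lethality within the complex, and the knockdown table combines loss of ARID2 with loss of SMARCA4. Knockdown of SMARCA4 in ARID2 knockout cells lowered 203 regions and raised 81 against the control knockdown in the same cells. The region on chromosome 10 from 121687715 to 121688416 rose to 34.6 ± 7.73 CPM (SD, n = 2) from 3.15 ± 1.8 (n = 2), a log2 fold change of 3.44 (adjusted p = 1.96e-05), and that on chromosome 4 from 39666464 to 39667303 rose by 2.93. The regions on chromosome 9 from 76970047 to 76970640, chromosome 2 from 194132121 to 194132946 and chromosome 12 from 74412381 to 74413133 fell by 3.13, 3.07 and 3.02, but without SMARCA4 knockdown replicate 2 their adjusted p was 0.115, 0.0505 and 0.0835, and for the first it was 0.0548 without control replicate 2. Of the 203 lower regions, 178 (87.7%) were lower in the SMARCA4 knockout of the knockout table (28.2 by chance), 23 in its ARID2 knockout (2.25 by chance), and 177 in the SMARCA4 knockdown of wild-type cells (10.1 by chance). The count was 44 without ARID2 knockout control replicate 1 and 79 without ARID2 knockout SMARCA4 knockdown replicate 2. It was 783 and 684 without replicates 1 and 2 of the SMARCA4 knockout with ARID2 knockdown, a group outside the contrast. With cyclic loess offsets it was 1076. With the replicate number as a block the count was larger too, and most of those regions were higher, as given with the processing. The majority of lower regions therefore depended on that choice.

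Knockdown of ARID2 in wild-type cells gave 0 called regions with edgeR and 0 with DESeq2, and 6167 at an unadjusted p of 0.05. In SMARCA4 knockout cells it gave 0 and 0, with 6524 at an unadjusted p of 0.05. With cyclic loess offsets these counts were 3 and 39, and the replicate number as a block also gave calls in both, as given with the processing. In SMARCA4 knockout cells, leaving out 5 of the 16 libraries gave calls: 65 regions without SMARCA4 knockout ARID2 knockdown replicate 2, and 2 without ARID2 knockout control replicate 2, either replicate of ARID2 knockout with SMARCA4 knockdown, or wild-type SMARCA4 knockdown replicate 1. On simulated data the ARID2 knockdown test found 2.99% of 2-fold and 72.7% of 4-fold changes. Across regions, ARID2 knockdown in wild-type cells correlated best with the ARID2 knockout among the 22 knockouts (r = 0.191). Negative values of like size stood for BCL11A (-0.182) and BCL11B (-0.179), so this value is weak evidence of an effect of the knockdown. The interactions, which ask whether a combined loss differs from the sum of single losses, gave 0 regions with edgeR and 0 with DESeq2 for both knockdowns in wild type (4803 at an unadjusted p of 0.05), ARID2 knockout with SMARCA4 knockdown (7564) and SMARCA4 knockout with ARID2 knockdown (4040). Without ARID2 knockout control replicate 2, or without replicate 2 of the SMARCA4 knockout with ARID2 knockdown, the interaction of ARID2 knockout and SMARCA4 knockdown had 1 region. This interaction test found 0% of simulated 2-fold and 16.7% of 4-fold changes, so interactions of that size were mostly not detectable at single regions here. Its median log2 value was 0.504 at the 1610 regions lower in the ARID2 knockout (17.1% below 0). It was 0.383 at the 20194 lower in the SMARCA4 knockout (26.2% below 0) and 0.0486 over all regions. At both lost sets the typical combined loss was thus smaller than the sum of single losses on the log2 scale, which was not tested. At regions higher in the SMARCA4 and ARID2 knockouts the medians were 0.156 and -0.0304. With the replicate number as a block, the interaction of ARID2 knockout and SMARCA4 knockdown also had calls.

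The regions lost in the knockout table were read in the knockdown libraries, relative to unchanged regions of like accessibility and to wild type with the control knockdown. The 20194 regions lower in the SMARCA4 knockout stood at -0.91 ± 0.0156 (log2, SD, n = 2) after SMARCA4 knockdown, -0.85 ± 0.00212 after the double knockdown, -0.17 ± 0.207 after ARID2 knockdown, -1.23 ± 0.0283 in SMARCA4 knockout cells and -1.27 ± 0.163 in those with ARID2 knockdown. In ARID2 knockout cells they stood at -0.41 ± 0.2 with the control and at -0.88 ± 0.178 with SMARCA4 knockdown. The 1610 regions lower in the ARID2 knockout stood at -0.24 ± 0.173 after ARID2 knockdown, -0.96 ± 0.0262 after SMARCA4 knockdown, -0.91 ± 0.00849 in ARID2 knockout cells, -0.89 ± 0.0283 after the double knockdown, -1.34 ± 0.0636 in ARID2 knockout cells with SMARCA4 knockdown, -1.31 ± 0.0849 in SMARCA4 knockout cells and -1.43 ± 0.269 in those with ARID2 knockdown. No test was made on these means, and an exact permutation test of 2 libraries against 2 cannot pass the threshold. The 990 regions higher in the ARID2 knockout stood at 0.41 ± 0.318 in ARID2 knockout cells, 0.36 ± 0.255 in ARID2 knockout cells with SMARCA4 knockdown and 0.17 ± 0.00636 after ARID2 knockdown. They stood at 0.18 ± 0.0283 in SMARCA4 knockout cells, 0.36 ± 0.177 in those with ARID2 knockdown and -0.03 ± 0.0494 after SMARCA4 knockdown, and the double knockdown had 0.00 ± 0.0426.

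**Figure D4:**
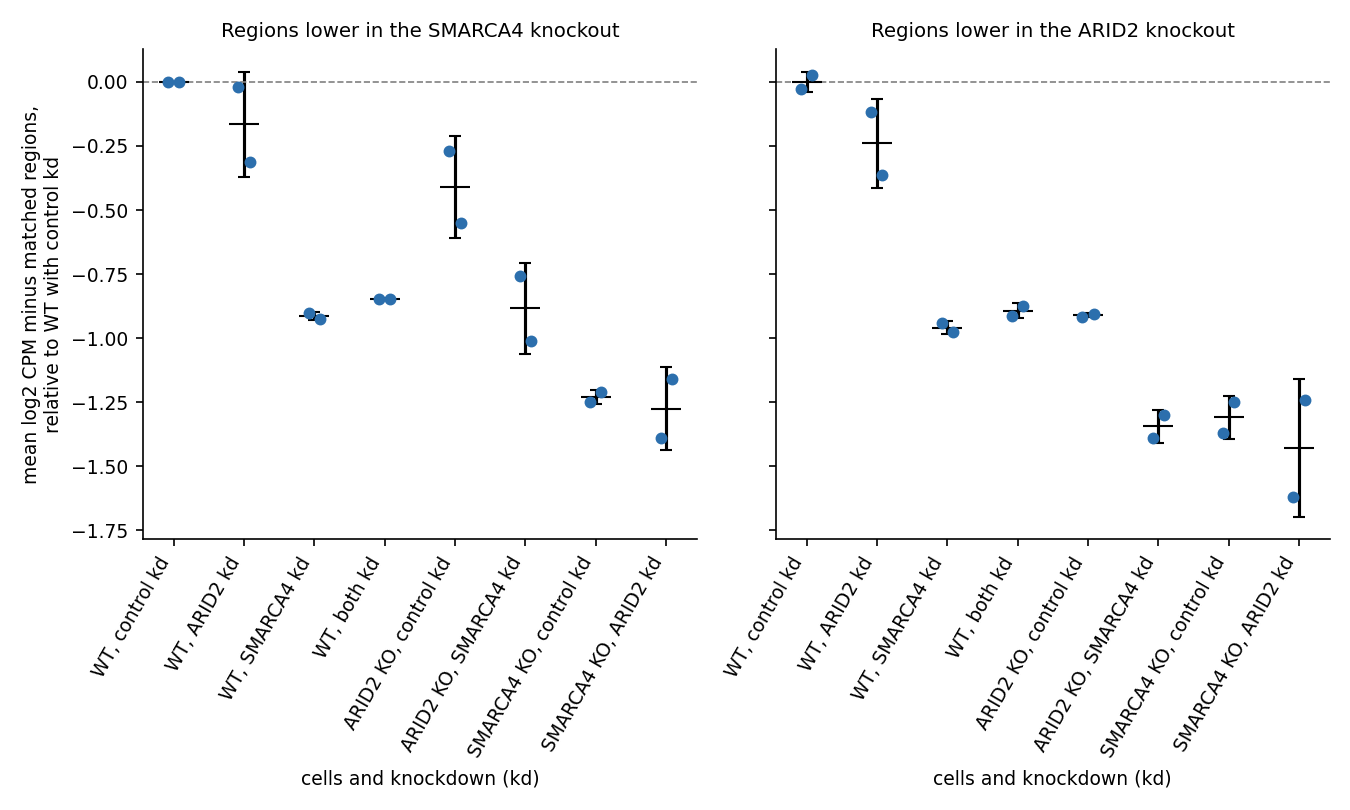
Mean log2 accessibility of the regions lower in the SMARCA4 knockout and of those lower in the ARID2 knockout, in each knockdown library, relative to wild type with the control knockdown. Points are libraries, lines are means of 2 and bars are SD, and ARID2-lower regions stand at -0.91 in ARID2 knockout cells and at -1.34 after SMARCA4 knockdown in them.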

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

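The tests of a state shared with the wild type of set 2, of gene loss alone, of shared cell lineage and of paralogous subunits were chosen only after the results were seen.

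Clones of the same gene differed by a test of the difference itself, at 326 regions for SMARCA4, 87 for ARID1A, 7235 for ARID1B and 6270 for BCL7B. At the chromosome X region from 102611074 to 102612335, the DPF3 knockout lay apart from the other BAF knockouts, with a gap of 0.713 of the range of the 5 values against a critical value of 0.71. This was 1 of 5 groups examined, and chance alone picks about 1 group in 20.

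ARID1B clone 7 and BCL7B clone 8 of set 1 had 13417 and 7030 called regions, where clone 5 and clone 10 of set 2 had 400 and 1081. Lower depth of set 2 as the whole cause is argued against by thinning set 1 clones and wild type to the mean total of the set 2 libraries, which left 10535 and 4950 called regions. Loss of the gene alone is argued against by the covariance between the clones of a gene, which was -0.0465 (ARID1B) and -0.182 (BCL7B) times the effect variance of the set 1 clone. A library or culture state shared with the wild type of set 2 stays open: the differences of ARID1B clone 7 and BCL7B clone 8 from the other set 1 clones correlated with the wild-type difference between sets at 0.491 and 0.418, but BCL11B reached 0.456, so this state cannot be told apart from variation common to several clones. Changes particular to single clones stay open too and were not tested.

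The BCL11A, BCL11B, SMARCD1 and SMARCD3 knockouts shifted the same regions, and all 4 clones lacked reads in the chromosome 10 stretch from 89472170 to 89697913. Paralogous subunits acting alike stays open as a cause. Among the clones lacking the stretch, 2 other pairs correlated more than a paralogous pair. BCL11B and SMARCD3 had 0.497, against 0.31 for SMARCD1 and SMARCD3 (differences of 0.0583 to 0.176 over 8 choices of single libraries). This comparison was chosen after correlations between these knockouts were seen. It restates the pattern and cannot decide the question. A cell lineage shared by the 7 clones without the stretch stays open: the other 3 of them, BCL7A, PHF10 and SMARCC1, had a mean correlation of -0.0869 with the 4, against -0.0786 for the 14 knockouts with the stretch (exact p = 0.531 over 680 choices of 3 knockouts, 1-sided). A shorter stretch on chromosome 13 from 98712525 to 98714700 lacked reads in the 4 and BCL7A alone. BCL7A shared 41.8% to 50.2% of its 275 lower regions with each of the 4, 63.6% with SMARCC1 and 53.8% with SMARCA4. These shares cannot be compared directly, since longer lists share more by chance. The 4 had 430 to 1185 lower regions each, SMARCC1 had 6094 and SMARCA4 had 20200. On chromosome 16, the stretch from 78512272 to 78830545 lacked reads in BCL11A, BCL11B, SMARCD3 and ARID1A clone 3, and part of it in BCL7A, SMARCC1, BRD9 and SMARCA2. It was not among the empty stretches of SMARCD1, and ARID1A clone 3 was not among the clones lacking the chromosome 10 stretch. Shared lineage cannot be told apart from effects of single genes, since there is 1 clone per gene.

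Regions higher in the SMARCA4 knockout were often among the most accessible, with an odds ratio of 2.61 against lower regions. An accessibility-dependent trend between libraries may account for it, since with cyclic loess offsets the ratio was 0.916. The 25% most accessible regions shifted by 0.23 and 0.19 in the SMARCA4 clones, where libraries of a group differed by a median of 0.13 and by up to 0.25, so that both shifts were larger than a typical difference between libraries. The comparison with library pairs was added after the first value was seen, and loess offsets would also remove a trend that belongs to the cells. Whether small changes are merely easier to call at accessible regions cannot be told apart, since among calls of at least 2-fold the ratio turned to 0.501 in place of moving near 1. In the knockdown table the ratio was 0.693 for the SMARCA4 knockout, and the 25% most accessible regions shifted by -0.0611, in the other direction.

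For the PBAF against BAF knockouts, 3 of 100 splits of the 9 knockouts, the real one included, gave at least the 2 called regions of the real split. That share lies under 0.05, but it does not exclude chance. The count was 1 without single knockouts such as ARID2, and other splits called more regions. The highest other split had 6 and set ARID2, BRD7, ARID1A and ARID1B against the rest, and that of ARID1B, DPF1, DPF2 and DPF3 had 3.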

How the results depend on the processing

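The normalized differences centred on their median, the removal of stretches and windows, and the alternatives of the SMARCA4 odds ratio were chosen only after results were seen, and the other alternatives were planned. DESeq2, RLE size factors and no expression filter left every count of the tested comparisons they were run on within 1.5 times its value, as did removing shifted chromosomes, or stretches and shifted windows, for the knockouts. Of 1354 refits of 78 named regions, 1337 kept direction and call, 17 lost the call at 13 regions, and 0 reversed. Of these 17, 6 were regions of the chromosome 10 stretch tested against the mean of the other knockouts, several of which lack reads there too.

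With pooled wild type the counts were 50441 (SMARCA4), 33443 (ARID1A), 17479 (SMARCC1), 11057 (ARID2) and a median of 3487 (other knockouts). With the other knockouts as reference they were 55772, 35409, 7613 (ARID2) and 5479 (median), and the lower share was 52.2% for SMARCA4, 65.4% for ARID1A, 38.6% for ARID2 and 68.9% for SMARCC1. On the normalized values they were 4448 (ARID2) and 2077 (median), and 4628 and 2081 when centred. With a 2-fold minimum, which by construction fewer regions pass, they were 18516 (SMARCA4, 80.6% lower) and 11153 (ARID1A). ARID1A clone 10 alone, with fewer libraries, had 12027. Cyclic loess offsets gave 1076 (SMARCA4 knockdown in ARID2 knockout), 1196 (ARID2 knockout, knockdown table), 3 and 39 (ARID2 knockdown in wild type and in SMARCA4 knockout), and an odds ratio of 0.916. Calls of at least 2-fold gave 0.501. The PBAF comparison had 17024 regions with single libraries, which takes libraries of a clone as independent. Except where the construction shows it, the cause was not tested.

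Replicate numbers were not taken as pairs. Differences of replicate 1 from replicate 2 correlated at a median of 0.237 (0.078 to 0.402) over 28 pairs of knockdown groups, 26 of them above 0.1. The median was 0.0162 in set 1. In all 8 knockdown groups this difference correlated positively with the mean difference of the other groups (r = 0.235 to 0.523). In the 24 groups of set 1 that r was -0.0467 to 0.117. With the replicate block, counts were 15375 (SMARCA4 knockdown in wild type, 75.2% lower), 12587 (double knockdown), 4172 (SMARCA4 knockdown in ARID2 knockout, 42.4% lower), 3875 (ARID2 knockout), 4 and 64 (ARID2 knockdown in wild type and in SMARCA4 knockout), and 2 (interaction of ARID2 knockout and SMARCA4 knockdown). Knockout counts stayed within 1.5 times.

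With single libraries left out, counts ranged over 19713 to 29922 (SMARCA4), 9674 to 16931 (ARID1A), 880 to 2164 (ARID2), 3303 to 5028 (SMARCC1) and medians of 285.5 to 853.5 (others). In the knockdown table they ranged over 2963 to 10029 (SMARCA4 knockdown), 1569 to 8169 (double), 6249 to 15734 (SMARCA4 knockout), 102 to 892 (ARID2 knockout), 44 to 783 (SMARCA4 knockdown in ARID2 knockout), 0 to 65 (ARID2 knockdown in SMARCA4 knockout) and 0 to 1 (interaction of ARID2 knockout and SMARCA4 knockdown), and over 1 to 5 for PBAF with single knockouts left out. A group left with 1 library is assumed to vary like the others. The libraries are named with the results. The overlap rule changed nothing, since the regions matched between the tables have the same coordinates and no 2 regions of the knockout table overlap. The estimated correlation of gene lists was not run, since no list could be tested. Of simulated 2-fold changes, all at regions of above-median accessibility, 41.8% were found for SMARCA4, 29.9% for ARID2 and 2.99% for ARID2 knockdown in wild type. Depth was not varied there. Thinned to the mean total of set 2, ARID1B clone 7 kept 10535 called regions in place of 13417.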

Other observations

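The knockout of SMARCD2, 1 of 3 alternative core paralogs, resembled PBAF knockouts at 2 regions. Its 616 called regions were 146 to 269 without any 1 of its own or the wild-type libraries of set 1. At the chromosome X region from 102611074 to 102612335 the SMARCD2 knockout had the highest level of all clones, 26.7 ± 4.46 CPM (SD, n = 2) against 8.25 ± 1.51 in wild type of set 1, and at the chromosome 4 region from 112694899 to 112695491 it had 5.67 ± 0.932 against 3.58 ± 0.157. BCL7B clone 8 of set 1 was also above wild type at both, with 16.4 ± 0.0297 and 5.19 ± 0.303 CPM, while BCL7B clone 10 of set 2 had 3.63 ± 0.525 and 1.85 ± 0.827 against 5.46 ± 0.993 and 3.23 ± 0.116 in wild type of set 2, so these levels were not particular to PBAF subunits and differed between clones of a gene. These values were looked up after the regions were known. Of the regions lower in the SMARCD2 knockout, 80.1% were also lower in the SMARCA4 knockout (234, with 40.5 by chance and 65.4 within bins of accessibility), which shares its wild-type libraries. With the median of all knockouts as reference, SMARCD2 correlated with ARID2 (0.3), SMARCA4 (0.28), ACTB (0.257), BRD7 (0.214) and PHF10 (0.209), not with PBRM1 (-0.0125), and had negative values with its paralogs SMARCD3 (-0.374) and SMARCD1 (-0.24).

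DPF2, a plant homeodomain finger subunit of canonical BAF, overlapped with SMARCA4 and ARID1A in calls of the same and of opposite direction. With the SMARCA4 knockout, 769 regions were called in opposite directions (329 by chance, 487 within 20 bins of accessibility), 375 were higher in both (165 and 276) and 284 lower in both (75.5 and 99.8). With ARID1A, 667 were called in opposite directions (224 and 389), 239 were higher in both (46.7 and 78) and 219 lower in both (56 and 77.5). Of the regions higher in the DPF2 knockout, 62.8% lay among the 25% most accessible, and these knockouts share their wild-type libraries. The correlations were 0.0632 and 0.0703 with wild type as reference, where shared controls alone gave 0.587 and 0.586, and -0.144 and -0.175 with the median of all knockouts. Without DPF2 replicate 1, wild-type replicate 2 or wild-type replicate 1, the DPF2 knockout had 345, 496 or 1236 called regions in place of 2604.

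Several clones lacked reads over runs of neighbouring regions. The chromosome 10 stretch from 89472170 to 89697913 held 15 to 32 counts in the BCL11A, BCL11B, BCL7A, PHF10, SMARCC1, SMARCD1 and SMARCD3 clones, where 2072 to 2311 were expected from wild type. The chromosome 9 stretch from 82170228 to 82975104 held 84 counts in SMARCC1 clone 12, with 5855 expected. A stretch on chromosome 16 from 78830044 to 79100975 held 0 counts in SMARCA4 clone 6 and in both SMARCA4 knockout groups of the knockdown table, and was not among the empty stretches of clone 4. Windows from 150 to 155 Mb of chromosome X were shifted by 0.93 in the BRD9 clone and by 0.91 in ARID1B clone 7, and the window from 20 to 25 Mb of chromosome 21 by -1.54 in ARID1B clone 7. That chromosome 21 window was also lower in several other clones, such as ACTB (-0.962) and BCL7B clone 8 (-0.806). No clone had it shifted upwards by more than 0.4. Chromosome 19 was shifted by 0.30 and 0.23 in the SMARCA4 clones, by 0.237 in ARID1A clone 3 and by -0.245 in BCL7B clone 8. SMARCA4 knockdown shifted it by 0.249 in wild-type and by 0.213 in ARID2 knockout cells.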
